A study of Homo sapiens with 12 samples.

How the data were processed

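SELEX-seq was analysed for the DNA-binding protein MEF2B, a MADS-box transcription factor, as wild type and as 4 variants with a single changed residue (K4E, K5E, R15G and K23R). In this assay a protein selects DNA from a random pool, and the bound DNA is amplified, sequenced and put through a further round. The labels give 12 samples. Of these, 10 have a processed table, 1 for each of the 5 proteins at round 1 and at round 2, and the 2 starting pools (round 0) were not analysed here. The wild type pool had a random region of 16 bp between fixed flanks, and bound and free DNA were separated on a gel, per the labels' protocols. The labels of the variants name 1 common starting pool and mark the protein as a DBD form, whereas those of wild type name another pool and no such form. Wild type and the variants were therefore treated as separate experiments.

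Adapters were trimmed with cutadapt 1.12, per the submitters' processing notes. The tool that counted the 10-mers and modelled the starting pool is not given in the sources used here. Per the file headers, each deposited table gives, for a 10-mer, its observed count, its probability, its expected count, its affinity and a standard error. The observed counts deposited by the authors are whole-number counts of 10-mer windows and are not normalized. The deposited probability is a fraction, the share of windows that the authors' model of the starting pool predicts for the 10-mer. The expected count is that fraction times the windows of the library, so it is a model value and not a measured count. The deposited affinity is a ratio: it was recomputed to within rounding as observed over expected count, with the square root taken at round 2, divided by the highest such value of the library. The deposited standard error is on the scale of that ratio and was recomputed from the affinity and the observed count.

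Expected count divided by probability gave 1 whole number per library, the number of 10-mer windows, which was divisible by 7 in each table. A 16 bp random region holds 7 windows of 10 bp, so the number of reads was taken as windows over 7. The labels give the length for the wild type pool only, so the reads of the variants rest on the assumption that their pool had the same length. Reads at rounds 1 and 2 came to 9866004 and 9886275 for wild type, 15544355 and 4286021 for K4E, 16337639 and 3480466 for K5E, 20990787 and 4211108 for R15G, and 14835190 and 3801783 for K23R. Each table lists only 10-mers with an observed count of at least 100. For a 10-mer of average expected count this minimum corresponds to 1.52-fold enrichment in both wild type libraries and to 0.71-fold to 1.01-fold in the variants at round 1. At round 2 it corresponds to 3.50-fold (K4E), 4.30-fold (K5E), 3.56-fold (R15G) and 3.94-fold (K23R). Poorly bound 10-mers are therefore missing to a different extent from each table, and a median over listed members of a list may be too high wherever members are unlisted.

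Enrichment was expressed as observed over expected count (fold over the model of the starting pool) and as log2 relative affinity. At round 1 these scales differ by a constant within a library, and at round 2 the affinity scale takes the square root. A margin is the median log2 relative affinity of a list minus the median of all listed 10-mers of the same library. The lists, the rule for naming 10-mers and the alternatives, except those said to be added, were fixed before the data were examined. The lists were the MEF2 site YTAWWWWTAR (64 10-mers), the same elements with a spacing of 3 (256) or of 5 (128), and the CArG box CCWWWWWWGG (64). The others were 10-mers of A or T only without a full match to YTAWWWWTAR (1008), of G or C only (1024) and of the fixed flanks (52). The list of A or T only keeps 10-mers that hold the core TAWWWWTA with other or missing outer bases. Here Y is C or T, R is A or G, and W is A or T. The outer base preference is the mean over the 16 centres WWWW of CTAWWWWTAG minus TTAWWWWTAA. Centres that are reverse complements of each other, such as AAAA and TTTT, give the same duplex, so the 16 centres are not 16 separate sites. SDs and counts over centres treat them as separate. The central TpA effect is the median over centres with a TpA step minus that over centres without one, among CTAWWWWTAG. The substitution profile sets each 10-mer of the site against the same 10-mer with 1 base changed, with positions counted from 1 at the 5' end.

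There was 1 library per protein and round, so no test across replicates was possible and no p-value is given. Rounds are successive selections and not replicates. Intervals are 95% intervals from 1000 Poisson resamples of the observed counts, or exact Poisson intervals for single 10-mers and exact binomial (Clopper-Pearson) intervals for shares. The Poisson intervals cover counting error only, because reads amplified without molecular identifiers are not independent molecules and windows of 1 read overlap. The intervals for shares treat 10-mers as independent draws, although both strands and shifted windows of 1 site can be among them. List medians were also placed among 10000 random lists of the same size, matched on deciles of expected count. The scatter between a 10-mer and its reverse complement, which are the same duplex, gave a second measure of technical error within a library. Variants that share a pool share its model, so agreement between variants was set beside simulated unselected libraries drawn from that pool. That simulation holds counting error and the count minimum but not errors of the pool model.

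Named 10-mers followed a fixed rule. They are the 5 highest affinities per library with reverse complements counted once, and, per variant against wild type at round 1, the 5 10-mers of the site with the largest increase and the 5 with the largest decrease. The latter were centred on the median of the site in each library and had to have a counting interval that excluded 0 and the same direction at round 2 where listed. The highest and lowest of the 16 centres per library, 4 fixed 10-mers (CTAAAAATAG, CTATTTATAG, CTATATATAG and TTAAAAATAA) and the substitutions with the largest and smallest loss complete the rule. Any 10-mer outside it is said to have been chosen after its values were seen.

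The alternatives were the mean of both strands, 10-mers listed in all libraries compared, enrichment without the root, a background without site-like 10-mers, the mean over a list, the list CTAWWWWTAG, all sites matched on flanks and the top 200 10-mers. A count minimum of 100 removed nothing, since that is the minimum of the tables. A minimum of 200, the library average as background, unlisted 10-mers set to a count of 99 and, for the outer base preference minus that of wild type, 10-mers listed in all 5 proteins were added after seeing the data.

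The code was tested on simulated libraries before use. At the depth of K4E round 1, a true outer preference of 2 was recovered as 2.00 over 100 simulations of 64 10-mers, and its interval held the true value in 98 of 100. At the depth of K4E round 2, a true preference of 2 was recovered as 2.00 and one of 3, which left 9.05 of the 16 TTAWWWWTAA 10-mers listed on average, as 2.99. Every simulated centre had the same preference, so these simulations cannot show an error from losing centres that differ in preference. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.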

Results

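SELEX-seq libraries were compared for 5 forms of MEF2B, the wild type protein and the variants K4E, K5E, R15G and K23R, each after round 1 and round 2 of selection. Each protein and round had 1 library, of 9866004 to 20990787 reads at round 1 and 3480466 to 9886275 reads at round 2. No value below has a replicate check. The intervals given cover counting error, except those of shares. The tables listed 143278 10-mers for wild type at round 1 and between 405651 (K23R) and 535951 (R15G) for the variants. At round 2 they listed 127720 for wild type and 22311 (K4E), 18598 (K5E), 50284 (R15G) and 26804 (K23R) for the variants. Wild type came from a separate experiment with its own starting pool, so a difference between a variant and wild type cannot be told apart from a difference between experiments. The variants share 1 pool and can be compared with each other more directly.

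Wild type MEF2B enriched its textbook site. The 64 10-mers of YTAWWWWTAR, the element that MEF2 proteins bind at muscle and other promoters, had a median enrichment of 7.98-fold at round 1 and 40.9-fold at round 2. Sites with C and G as outer bases were the better ones, with medians of 9.64-fold for CTAWWWWTAG and 5.45-fold for TTAWWWWTAA at round 1, and of 58.2-fold and 19.8-fold at round 2. The site stood 2.12 log2 units above the listed 10-mers at round 1 (interval 2.09 to 2.16) and 2.00 above at round 2 (1.99 to 2.01), higher than all 10000 random lists in both libraries. On 10-mers listed in all 5 proteins the round 2 margin was 0.94. The highest affinity at round 2 was that of CTAAAAATAG, with 5368 windows observed and 66.95-fold enrichment. TAAAAATAGC (66.4-fold), CTATTTTTGG (65.3-fold), CTATTTATAG (65.0-fold) and CCCAAAATAG (64.5-fold) followed. At round 1 the highest were CAAAAATAGA (11.3-fold), CCCGAAATAA, CCCAAAATAG, GCTATAAATA and ACCGAAATAG (10.9-fold), of which only GCTATAAATA holds the whole core TAWWWWTA. Their relative affinities lay between 0.965 and 1, with standard errors of 0.045 to 0.051, so that their order was not resolved at this depth.

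All 4 variants also enriched the site over the starting pool. At round 1 the median over YTAWWWWTAR was 12.4-fold in R15G, 5.59-fold in K5E, 4.48-fold in K23R and 3.70-fold in K4E. In K4E and K5E the low medians came from sites with other outer bases: their CTAWWWWTAG sites were enriched 11.01-fold and 13.2-fold, more than the 9.64-fold of wild type. Their TTAWWWWTAA sites reached only 1.58-fold and 2.26-fold. R15G enriched both kinds of site strongly, 13.3-fold and 10.2-fold, and K23R enriched both weakly, 4.25-fold and 4.52-fold. Margins of the site over the listed 10-mers at round 1 were 1.84 in K4E, 2.45 in K5E, 3.73 in R15G and 2.10 in K23R, each above all 10000 random lists. These margins rest on backgrounds that differ with the depth of the table. The margin of K5E was 0.33 above that of wild type, but the difference was -0.51 when the library average, an alternative added after seeing the data, was the background.

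**Figure D1:**
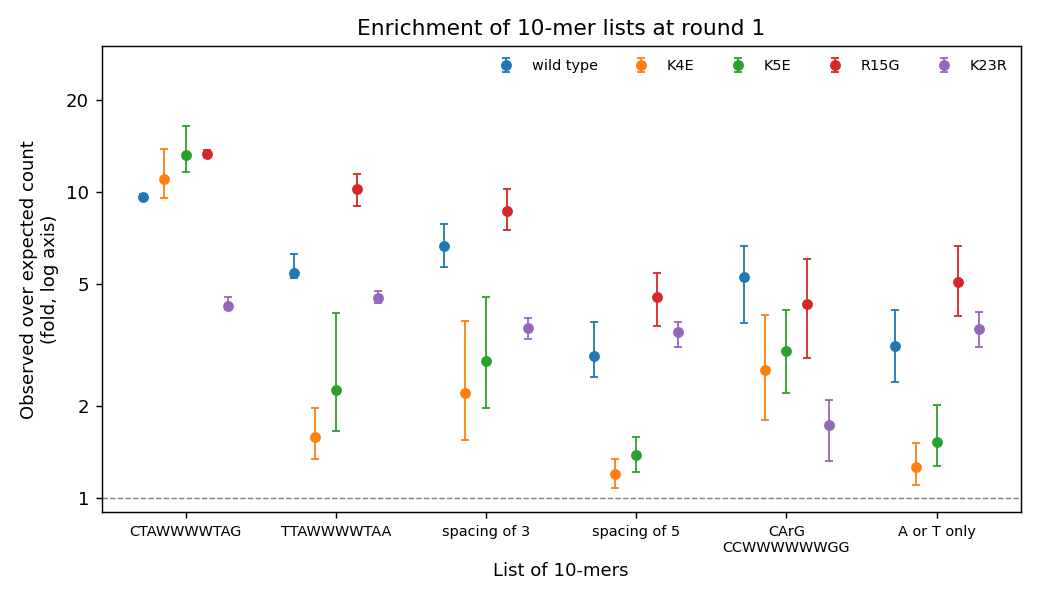
Enrichment of 6 lists of 10-mers at round 1 (y axis, observed over expected count, log scale) for the 5 proteins. Points are medians over the listed members and bars span the quartiles; K4E and K5E enriched TTAWWWWTAA 1.58-fold and 2.26-fold against 10.2-fold in R15G.

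The clearest difference among the proteins lay at the outer bases of the site. With the centre held fixed, CTAWWWWTAG exceeded TTAWWWWTAA by 2.75 log2 units in K4E at round 1 (SD 0.26 over 16 centres, interval 2.70 to 2.80), a 6.73-fold ratio. The preference was 2.40 in K5E (SD 0.41, interval 2.36 to 2.45), 0.80 in wild type (SD 0.25, 0.76 to 0.84) and 0.44 in R15G (SD 0.30, 0.42 to 0.47). In K23R it was -0.053 (SD 0.11, interval -0.096 to -0.0099), with the C and G form higher at only 4 of 16 centres. In each of the other 4 proteins the C and G form was higher at all 16 centres. Centres that are reverse complements of each other are 1 site read on both strands, so these 16 values are not all independent. The enrichment of TTAAAAATAA at round 1, which also reflects the weak enrichment of all sites in K23R, was 11.4-fold in R15G, 7.17-fold in wild type, 5.02-fold in K5E, 4.64-fold in K23R and 2.998-fold in K4E. With 1 outer base changed, the median of CTAWWWWTAA was 8.28-fold in wild type, 3.51-fold in K4E, 5.79-fold in K5E, 12.4-fold in R15G and 4.52-fold in K23R.

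At round 2 the preference was 2.82 in K4E and 2.03 in K5E, from the 5 and 6 of 16 centres whose TTAWWWWTAA form was still listed. It was 0.79 in wild type, 0.91 in R15G and 0.21 in K23R, each from 16 centres, but 0.51, 0.48 and 0.062 on the 5 centres listed in all 5 proteins. Against wild type, K4E lay higher by 1.95 (interval 1.89 to 2.02) at round 1 and by 2.04 (1.99 to 2.08) at round 2, and K5E by 1.60 (1.55 to 1.66) and 1.25 (1.21 to 1.29). On centres listed in both the variant and wild type, the round 2 differences were 2.32 in K4E and 1.48 in K5E. The lower round 2 value of K5E came with the change of centres, since on the 6 centres listed at both rounds its preference was 2.00 at the first step and 2.06 at the second. K23R lay lower at both rounds, with differences of -0.85 (-0.91 to -0.80) and -0.57 (-0.60 to -0.55). R15G changed side, from -0.36 (-0.40 to -0.31) at round 1 to 0.13 (0.11 to 0.14) at round 2. On the 5 centres listed in all 5 proteins at round 2, an alternative added after seeing the data, R15G minus wild type was -0.027 and K23R minus wild type -0.44. The side of R15G at round 2 thus depended on the centres used. These centres were set by the count minimum in other proteins, and no round 1 difference was taken on them. They therefore cannot show whether the change of side between rounds was stable. Among the variants, K5E differed from K4E by -0.35 at round 1 (-0.42 to -0.29), R15G by -2.31 (-2.37 to -2.25) and K23R by -2.80 (-2.87 to -2.74).

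**Figure D2:**
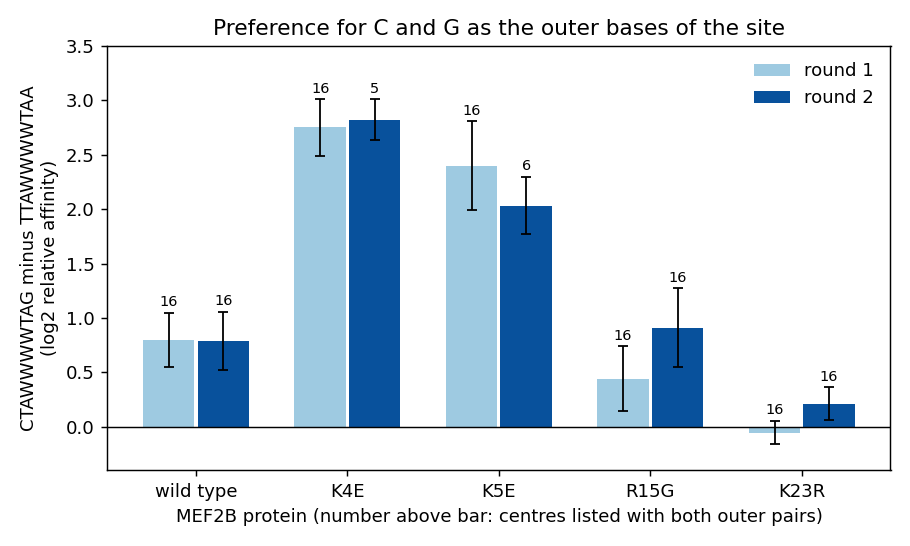
Outer base preference (y axis, CTAWWWWTAG minus TTAWWWWTAA in log2 relative affinity) of the 5 proteins at round 1 and round 2; bars are means over matched centres, error bars are the SD over centres, and the number above each bar counts the centres. K4E and K5E lie between 2.03 and 2.82, and the other proteins between -0.053 and 0.91.

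Among CTAWWWWTAG sites, the choice between A and T at the 4 central bases mattered in K4E and K5E and less in the other proteins. This does not extend to TTAWWWWTAA, which at round 1 spanned 3.01-fold to 7.17-fold in wild type and 5.66-fold to 12.98-fold in R15G. Its span was 1.02-fold to 2.998-fold in K4E, 1.22-fold to 5.23-fold in K5E and 3.51-fold to 4.995-fold in K23R. Over the 16 CTAWWWWTAG sites at round 1, log2 relative affinity spanned 1.88 in K4E and 1.76 in K5E, against 0.29 in wild type, 0.18 in R15G and 0.46 in K23R. CTAATATTAG was the lowest of the 16 in wild type, K4E, K5E and K23R at both rounds and in R15G at round 2. Its enrichment at round 1 was 4.77-fold in K4E (interval 4.37 to 5.20) and 5.33-fold in K5E (4.92 to 5.77). The highest at round 1 were CTAAAAATAG in K4E (17.5-fold, 16.6 to 18.5) and in wild type (10.5-fold, 9.77 to 11.2), and CTATAAATAG in K5E (18.1-fold, 17.2 to 19.0) and K23R (5.12-fold, 4.65 to 5.62). In R15G the highest was CTATAATTAG (14.0-fold, 13.4 to 14.6) and the lowest CTAAAAATAG (12.3-fold, 11.7 to 13.0). At round 2 the highest were CTAAAAATAG in wild type, CTATAAATAG in K4E, K5E and R15G, and CTATTTATAG in K23R (31.0-fold).

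Centres with a TpA step differed from those without one by less than the spread of the centres in K4E and K5E. The difference was more than that spread in R15G at round 1 and slightly more in K23R at round 2. Among CTAWWWWTAG, the 11 centres with such a step exceeded the 5 without one by 0.30 in K5E at round 1 (interval 0.21 to 0.40) and by 0.42 at round 2 (0.37 to 0.45). These intervals leave out the spread over centres. In K5E at round 1 the SD was 0.47 with the step and 0.44 without it, and in K4E at round 2 it was 0.58 and 0.49. Both groups hold centres that are reverse complements of each other, so they contain fewer separate sites than centres. In R15G the difference was 0.11 (0.055 to 0.15) at round 1, with SDs of 0.033 and 0.042, and 0.097 (0.074 to 0.12) at round 2, with SDs of 0.10 and 0.060. In wild type both intervals included 0 (-0.026 and 0.011). In K4E and K23R the interval included 0 at round 1 (-0.080 and 0.030) and not at round 2 (0.11 and 0.152). The SDs of K23R at round 2 were 0.141 and 0.141. Over all YTAWWWWTAR matched on flanks the difference was 0.49 in K5E and 0.031 in K4E at round 1, and 0.23 in R15G and 0.10 in wild type at round 2. CTATATATAG, with TpA steps throughout, was enriched 9.65-fold in wild type, 10.3-fold in K4E, 14.4-fold in K5E, 13.7-fold in R15G and 4.51-fold in K23R at round 1. CTATTTATAG was enriched 9.63-fold, 15.4-fold, 17.4-fold, 13.9-fold and 4.62-fold in the same order.

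**Figure D3:**
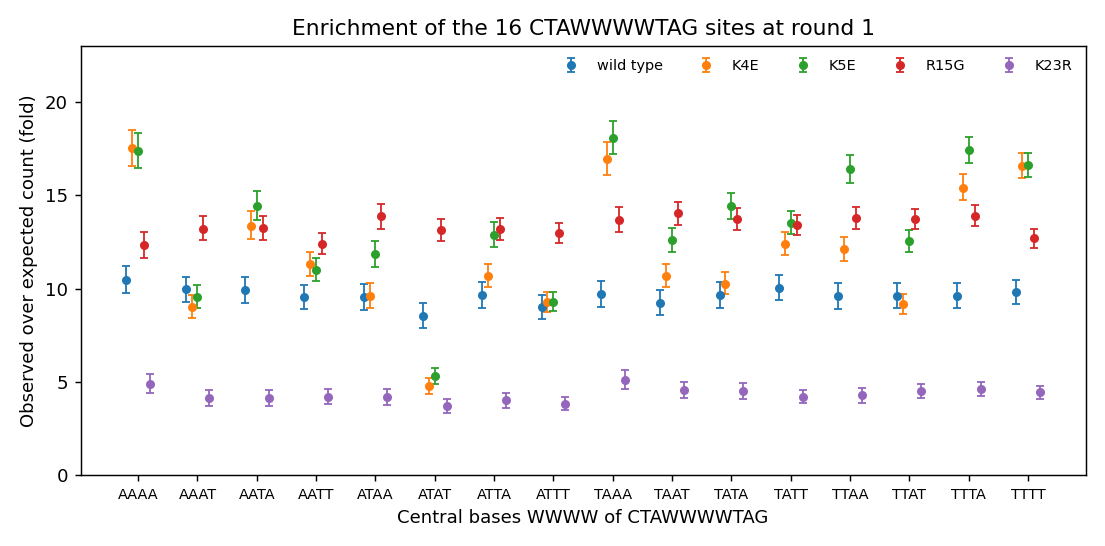
Enrichment (y axis, observed over expected count) of the 16 CTAWWWWTAG sites at round 1, by their central bases (x axis), for the 5 proteins with exact Poisson intervals. K4E spans 4.77-fold to 17.5-fold and K5E 5.33-fold to 18.1-fold, whereas R15G stays between 12.3-fold and 14.0-fold.

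Substitution of single bases showed where each protein depended on the site. G at position 2, in place of the T of the first TA step, gave the largest loss at round 1 in wild type (-1.70, SD 0.52 over matched 10-mers), K4E (-2.15, SD 1.11), K5E (-2.35, SD 0.98) and R15G (-2.16, SD 0.45). In K23R the largest loss was that of G at position 4 (-0.997, SD 0.34), and G at position 2 cost -0.57. Only 19 of 64 10-mers with G at position 2 were listed for K4E and 34 for K5E, so these means rest on part of the 10-mers. C at position 9 is the same change read on the other strand. It was listed for all 64 in both variants and averaged -1.87 in K4E and -2.17 in K5E. C at position 2 was tolerated better in each protein, with changes of -0.30 in wild type, -0.69 in K4E, -0.89 in K5E, -0.69 in R15G and -0.44 in K23R. Averaged over positions 1 and 10, a base outside Y or R cost -1.02 in K4E and -0.87 in K5E, against -0.16 in wild type, -0.20 in R15G and -0.054 in K23R. The TA steps averaged -1.42 in K4E, -1.60 in K5E, -1.28 in R15G, -0.95 in wild type and -0.55 in K23R. A G or C at the central positions 4 to 7 averaged -1.63 in K4E, -1.68 in K5E, -1.22 in R15G, -0.91 in wild type and -0.83 in K23R. The unsubstituted sites started from different medians, 3.70-fold in K4E, 5.59-fold in K5E, 12.4-fold in R15G, 7.98-fold in wild type and 4.48-fold in K23R. Sites already near 1-fold, such as TTAWWWWTAA in K4E (1.58-fold), had little left to lose. Sizes of loss are therefore not directly comparable between proteins. The smallest losses were G at position 1 in wild type (-0.049), C at position 2 in K4E (-0.69), A at position 1 in K5E (-0.70), and T at position 10 in R15G (-0.18) and K23R (0.018). At round 2 only 26.4% and 28.2% of the substituted 10-mers were listed for K4E and K5E, so their profiles were not compared there.

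**Figure D4:**
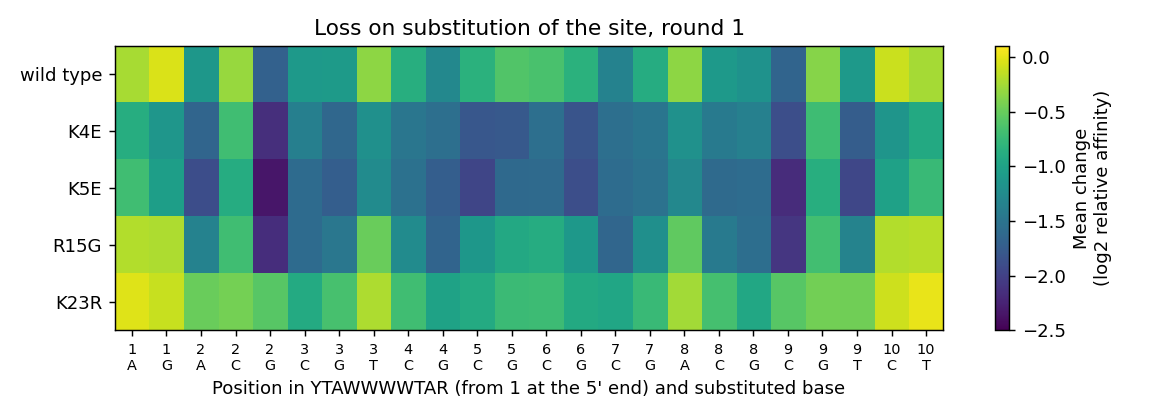
Mean change in log2 relative affinity (colour) when 1 base of YTAWWWWTAR was replaced, by position and new base (x axis), for the 5 proteins at round 1. G at position 2 ranges from -0.57 in K23R to -2.35 in K5E.

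Lists of A or T only and of the spacings were enriched least in K4E and K5E, whereas the CArG box had its lowest fold in K23R. At round 1, 10-mers of A or T only were enriched 5.09-fold in R15G, 3.56-fold in K23R and 3.14-fold in wild type, but 1.53-fold in K5E and 1.27-fold in K4E. This list still holds 10-mers with the core TAWWWWTA, such as ATAWWWWTAT, so it is not free of partial sites. The spacing of 5 gave 4.55-fold in R15G, 3.48-fold in K23R and 2.92-fold in wild type, against 1.38-fold in K5E and 1.20-fold in K4E. With a spacing of 3 the medians were 8.70-fold in R15G, 6.65-fold in wild type, 3.61-fold in K23R, 2.80-fold in K5E and 2.20-fold in K4E. CCWWWWWWGG, the CArG box bound by the related factor SRF, was enriched 5.29-fold in wild type, 4.32-fold in R15G, 3.04-fold in K5E, 2.62-fold in K4E and 1.73-fold in K23R. K23R enriched all sites weakly, and as a share of the CTAWWWWTAG median, a measure chosen after the values were seen, the CArG box reached 54.8% in wild type, 40.8% in K23R, 32.5% in R15G, 23.8% in K4E and 23.004% in K5E. At round 2, 58 of its 64 10-mers were listed for wild type, 41 for K4E, 37 for K5E, 38 for R15G and 5 for K23R.

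Controls without a site were not enriched. Listed 10-mers of G or C only had medians of 0.86-fold in K4E, 0.75-fold in K5E, 0.58-fold in R15G and 0.76-fold in K23R at round 1, and none were listed for wild type. Between 105 and 193 of 1024 were listed in the variants, and these medians hold for the listed members only. Listed 10-mers of the fixed flanks had medians of 1.02-fold in K4E, 0.97-fold in K5E, 0.76-fold in R15G and 1.00-fold in K23R, from 5 to 14 of 52.

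Consensus 10-mers that set each variant apart from wild type were then named at round 1, relative to the median of the site in each library. In K4E, 17 of 36 sites were higher and 14 lower beyond counting error. Of these, 4 had the opposite direction at round 2 and 8 of the lower ones were not listed there. The highest were CTAAAAATAG (1.86, interval 1.78 to 1.94), CTATAAATAG (1.85), CTAAATATAG (1.48), CTATTAATAG (1.45) and CTAAATTTAG (1.36), and the lowest was CTAATATTAA (-0.9985, interval -1.17 to -0.83). TTAATTATAA, TTATATATAA, TTAAATTTAA and TTAATAATAA followed (-0.92 to -0.79). K5E had 17 higher and 15 lower, led by CTATAAATAG (1.39, 1.31 to 1.47), CTATTAATAG (1.29), CTAAAAATAG (1.26), CTATATATAG (1.09) and CTAAATATAG (1.00). Its lowest was TTAAAATTAA (-1.29, -1.45 to -1.12), before TTAAATTTAA, TTAATTATAA, CTAATATTAA and TTAATAATAA. At round 2, 3 of its sites had the opposite direction and 7 of the lower ones were not listed. None of the 5 lowest sites named for K4E or for K5E was listed at round 2.

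In K23R the named higher sites were of the TTAWWWWTAA form and the named lower ones of the CTAWWWWTAG form. In this variant 13 sites were higher and 13 lower, and all 26 had the same direction at round 2. TTAATATTAA was the highest (1.05, interval 0.85 to 1.26), followed by TTATATATAA (0.68), TTAATAATAA (0.64), TTAAAATTAA (0.59) and TTAAATTTAA (0.54). CTAAATATAG was the lowest (-0.43, -0.55 to -0.31), before CTAAAATTAG (-0.42), CTAATATTAG (-0.37), CTAAATTTAG (-0.35) and CTATTAATAG (-0.33). TTAATATTAA was nevertheless the least enriched of the 64 10-mers of the site at round 1, in K23R (3.51-fold) and in wild type (3.01-fold). Those 10-mers spanned only 3.51-fold to 5.12-fold in K23R, against 3.01-fold to 10.47-fold in wild type. These differences, and their shared direction at round 2, can therefore reflect the order of sites within wild type. In R15G the differences were smaller, from TTATAAATAA (0.28, 0.19 to 0.36), TTATTAATAA (0.26), CTATATATAA (0.20) and CTAATAATAA (0.14) to CTAAAAATAG (-0.33, -0.42 to -0.25). CTAAATTTAG (-0.26), CTATTTTTAA (-0.22), CTAAAATTAG (-0.17) and CTAAATTTAA (-0.16) were also lower. Of its 11 higher and 12 lower sites, 13 changed direction at round 2.

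The best 10-mers of each library reflected these differences. Of the 50 highest affinities at round 1, 98.0% held the core TAWWWWTA in K23R (interval 89.4 to 99.9), 92.0% in R15G (80.8 to 97.8), 52.0% in K5E (37.4 to 66.3), 38.0% in K4E (24.7 to 52.8) and 24.0% in wild type (13.1 to 38.2). In wild type this share was 68.0% (53.3 to 80.5) at round 2. These intervals treat the 50 10-mers as independent, which both strands and shifted windows of 1 site are not, and do not measure counting error. K4E led with CTAAAAATAG, CTATAAATAG, CCCAAAATAG (16.8-fold), CTATTTTTGG (15.5-fold) and CTATTTTCGG (13.5-fold) at round 1. At round 2 it led with CTATAAATAG (396-fold), CTATTTTTAG, CCCAAAATAG, CTATTTTTGG and CTAAATATAG. K5E led with CTATAAATAG, CTAAAAATAG, CTATTAATAG, CCCAAAATAG and CCAAAAATAG at round 1 and with CTATAAATAG (200.4-fold), CTATTTTTAG, CTATTAATAG, CTATTTTTGG and CTATTTTGGG at round 2. R15G led with TTATAAATAG (14.3-fold), TATTTATAGT, GTTATTTATA, CTATAAATAC and CCATAAATAG at round 1. At round 2 its highest were CTATAAATAG (185-fold), CTATATATAG, CTAAATATAG, TATAAATAGC and CTATTAATAG. In K23R the highest were AATAAAAATA (5.42-fold), TTATTTTTAT, TATATTTATA, GTTATTTTTA and GTATTTATAT at round 1, and TTATTTATAT (32.6-fold), CTATTTATAT, TATTTATATA, GTTATTTTTA and TCTATTTATA at round 2.

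Rounds of 1 protein ranked 10-mers alike, though less so in K23R among consensus sites. Spearman correlations of log2 relative affinity across the 10-mers listed at both rounds were 0.861 in wild type, 0.758 in K4E, 0.824 in K5E, 0.828 in R15G and 0.834 in K23R. Between proteins at round 1 the highest were R15G with K23R (0.866), wild type with R15G (0.850) and K4E with K5E (0.777), and the lowest were wild type with K23R (0.589) and with K4E (0.613). Each pair rests on its own set of 10-mers, and with a count minimum of 200, added after seeing the data, K4E with K5E was the highest (0.945), before R15G with K23R (0.845). At round 2 K4E and K5E gave 0.886 and K4E and K23R 0.485. Simulated unselected libraries from the shared pool gave at most 0.048 among the variants at round 1. For K4E and K5E the covariance was 0.132 against 0.00055 simulated. 10-mers are not independent replicates, and part of the agreement among variants may stem from the pool model they share. Among consensus sites alone, K23R ranked differently at round 1, with a correlation of 0.027 with wild type and 0.165 with K4E at round 1. At round 2 these were 0.681 and 0.489. Between its own rounds K23R reached 0.627 over these sites, against 0.897 to 0.995 in the other proteins, so its order among them was not stable between rounds.

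Each 10-mer and its reverse complement differed with an SD of 0.205 to 0.254 in log2 relative affinity at round 1. Counting error alone would give 0.149 to 0.175. At round 2 the SD was 0.131 to 0.291, against 0.068 to 0.076 from counting. Over all listed pairs, counting intervals therefore understate the technical error, and more so at round 2. Over the 28 pairs of consensus sites the SD was 0.092 in wild type, 0.197 in K4E, 0.102 in K5E, 0.054 in R15G and 0.091 in K23R at round 1. At round 2 it was 0.028, 0.058, 0.079, 0.046 and 0.055 in the same order, with 23 pairs in K4E and in K5E. Counting error was not computed for consensus pairs alone, so how far the intervals of consensus sites understate the error is not known.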

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

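The tests of 10-mers missing from the round 2 list, of one common shift between experiments and of wild type as a separate experiment were chosen after the result was seen, and the other tests before.

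The outer base preference departed from wild type in opposite directions, at both rounds, in different variants. K4E minus wild type was 1.95 at round 1 and 2.04 at round 2, K5E minus wild type was 1.60 and 1.25, and K23R minus wild type was -0.85 and -0.57. The round 2 values of K4E and K5E set 5 and 6 centres against 16 in wild type. On matched centres both of these differences were larger, as given above. The consensus margin also departed both ways, with K4E minus wild type at -0.28 and -0.72 and R15G minus wild type at 1.61 and 0.082. With 1 library per protein and round, these differences between variants were not tested across replicates. The directions of the margins rest on the background. K4E minus wild type became 0.58 at round 1 with a count minimum of 200 and 0.11 at round 2 with 10-mers listed in all proteins. R15G minus wild type became 0.51 at round 1 with the latter and -0.018 at round 2 with both strands.

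At round 1 the outer base preference spanned 2.80 log2 units over the 4 variants, from -0.053 in K23R to 2.75 in K4E. Counting noise and loss of centres at lower depth do not account for this. After thinning of each library to the fewest reads the range was 2.82, with at least 15 centres left per variant. Thinning scaled observed and expected counts alike, so it could not show any other effect of depth. Errors specific to a strand were far too small, since the range was 35.2 times the SD of the preference between strands. At round 1 TTAWWWWTAA in K4E lay near 1-fold (1.58-fold). In R15G and K23R, CTAWWWWTAG (13.3-fold and 4.25-fold) lay near the highest enrichment of any listed 10-mer, 14.3-fold and 5.42-fold. How far such limits at either end changed the range was not tested. The preparation of each protein, with 1 library each, stays open and was not tested. A change of DNA contacts by the substituted residue is a hypothesis that remains among the open explanations.

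The variants differed from wild type in a setting where wild type was a separate experiment. A single shift common to all variants is excluded as the only cause, because 2 variants lay below wild type at round 1 and the others above. Such a shift on top of differences among the variants would give the same signs and is not excluded. The experiment itself cannot be told apart from variant status, since 0 wild type libraries share the source label of the variants. The labels also mark the variants, and not wild type, as a DBD form.

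In R15G the outer base preference was larger at round 2 (0.91) than at round 1 (0.44). On matched centres and the same scale, the preference also rose in K23R (by 0.27) and in K4E (by 0.22). The second step exceeded the first there at 15 of 16 and 5 of 5 centres, so a rise was not particular to R15G. Both strands of a site count here as separate centres. The change was 0.030 in K5E and -0.012 in wild type, and the rise was largest in R15G. Missing 10-mers do not account for the rise in R15G, since all 16 centres were listed at both rounds and gave an increase of 0.47 on this scale. Saturation of the best sites at round 1 could produce such an increase. The slope of the second selection step on the first was steeper by 0.94 among the better classes of sites, but its interval (-0.060 to 2.39) over 11 classes leaves this unresolved.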

How the results depend on the processing

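The count minimum of 200, the library average as background, unlisted 10-mers set to a count of 99 and the outer base differences on 10-mers listed in all 5 proteins were chosen only after the result was seen, and the other alternatives before.

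Of 562 alternative values, 264 stayed the same, 287 moved and 11 reversed direction. The count of unchanged values is not a measure of stability, because 182 of the 562 were identical to the main value where an alternative left the 10-mers or the scale as they were. The direction of the outer base preference was the same under each alternative, but 35 of its 50 values were identical in this way. Averaging strands cannot alter it, and leaving out the root only rescales it. Except for 1, the directions that reversed were those of margins, which rest on the background. The exception was the outer base preference of R15G minus wild type at round 2, which became -0.027 on 10-mers listed in all 5 proteins. For the consensus margin minus that of wild type they were K5E at round 1 with the library average (-0.51) and with common 10-mers (-0.054), K4E at round 1 with a minimum of 200 (0.58), K4E at round 2 with common 10-mers (0.11) and R15G at round 2 with both strands (-0.018). The others were the spacing of 5 in K4E at round 1 (-0.022 and -0.087), in K5E at round 1 (-0.076) and in R15G at round 2 (-0.084), and A or T only in K4E at round 1 (-0.0062). The cause of these moves was not tested, except where the construction shows it. The planned count minimum of 100 removed nothing and gave no separate values.

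Values averaged over both strands moved as follows. The consensus margin was, at round 1, 2.00 (wild type), 1.61 (K4E), 2.13 (K5E), 3.22 (R15G) and 1.55 (K23R), and at round 2, 1.91 (wild type), 0.99 (K4E), 0.76 (K5E), 1.89 (R15G) and 0.89 (K23R). The margin of the spacing of 3 was, at round 1, 1.72 (wild type), 0.86 (K4E), 1.13 (K5E), 2.70 (R15G) and 1.23 (K23R), and at round 2, 1.48 (wild type), 0.35 (K4E), 0.18 (K5E), 0.93 (R15G) and 0.26 (K23R). The margin of the spacing of 5 was, at round 1, 0.54 (wild type), -0.022 (K4E), 0.13 (K5E), 1.77 (R15G) and 1.17 (K23R), and at round 2, 0.29 (wild type), -0.084 (R15G) and 0.051 (K23R). The CArG margin was, at round 1, 1.40 (wild type), 1.07 (K4E), 1.23 (K5E), 1.71 (R15G) and 0.20 (K23R), and at round 2, 0.90 (wild type), 0.29 (K4E), 0.12 (K5E) and 0.18 (R15G). The margin of A or T only was, at round 1, 0.62 (wild type), 0.060 (K4E), 0.25 (K5E), 1.92 (R15G) and 1.21 (K23R), and at round 2, 0.53 (wild type), -0.24 (K4E), -0.22 (K5E), 0.23 (R15G) and 0.10 (K23R). The margin of the fixed flanks was, at round 1, 0.18 (K5E). The consensus margin minus that of wild type was, at round 1, -0.40 (K4E), 0.12 (K5E), 1.22 (R15G) and -0.45 (K23R), and at round 2, -0.91 (K4E), -1.15 (K5E), -0.018 (R15G) and -1.01 (K23R).

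Restriction to 10-mers listed in all libraries compared, 100088 at round 1 and 9311 at round 2, moved these values. For the consensus margin, the values were, at round 1, 1.99 (wild type), 1.53 (K4E), 1.94 (K5E), 2.498 (R15G) and 1.41 (K23R), and at round 2, 0.94 (wild type), 1.04 (K4E), 0.83 (K5E), 1.44 (R15G) and 0.93 (K23R). For the margin of the spacing of 3, the values were, at round 1, 1.73 (wild type), 0.79 (K4E), 0.94 (K5E), 1.99 (R15G) and 1.10 (K23R), and at round 2, 0.67 (wild type), 0.43 (K4E), 0.22 (K5E), 0.69 (R15G) and 0.44 (K23R). For the margin of the spacing of 5, the values were, at round 1, 0.54 (wild type), -0.087 (K4E), -0.076 (K5E), 1.05 (R15G) and 1.05 (K23R), and at round 2, 0.32 (wild type), -0.74 (K4E), -0.54 (K5E), 0.21 (R15G) and 0.49 (K23R). For the CArG margin, the values were, at round 1, 1.42 (wild type), 1.07 (K4E), 1.118 (K5E), 1.08 (R15G) and 0.046 (K23R), and at round 2, 0.50 (wild type), 0.65 (K4E), 0.40 (K5E), 0.14 (R15G) and 0.00029 (K23R). For the margin of A or T only, the values were, at round 1, 0.66 (wild type), -0.0062 (K4E), 0.074 (K5E), 1.22 (R15G) and 1.08 (K23R), and at round 2, 0.43 (wild type), -0.37 (K4E), -0.13 (K5E), 0.79 (R15G) and 0.78 (K23R). The outer base preference was, at round 2, 0.51 (wild type), 1.93 (K5E), 0.48 (R15G) and 0.062 (K23R). The mean loss at positions 1 and 10 was, at round 2, -0.094 (wild type), -0.21 (R15G) and -0.072 (K23R). The mean loss at the TA steps was, at round 2, -0.52 (wild type), -1.07 (R15G) and -0.55 (K23R). The mean loss at positions 4 to 7 was, at round 2, -0.41 (wild type), -0.80 (R15G) and -0.70 (K23R). For the consensus margin minus that of wild type, the values were, at round 1, -0.46 (K4E), -0.054 (K5E), 0.51 (R15G) and -0.58 (K23R), and at round 2, 0.11 (K4E), -0.10 (K5E), 0.50 (R15G) and -0.011 (K23R). The outer base preference minus that of wild type was, at round 2, 2.32 (K4E) and 1.48 (K5E), on 10-mers listed in the variant and in wild type. On 10-mers listed in all 5 proteins, added after seeing the data, it was, at round 2, 2.32 (K4E), 1.43 (K5E), -0.027 (R15G) and -0.44 (K23R).

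A background without site-like 10-mers moved 1 kind of result. Values of the consensus margin were, at round 1, 2.22 (wild type), 3.83 (R15G) and 2.17 (K23R), and at round 2, 2.08 (wild type), 1.34 (K4E), 2.20 (R15G) and 1.20 (K23R).

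Means were also taken in place of medians over the list. The consensus margin was, at round 1, 2.05 (wild type), 2.04 (K4E) and 3.67 (R15G), and at round 2, 1.93 (wild type), 1.41 (K4E), 1.16 (K5E), 1.97 (R15G) and 1.04 (K23R).

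Use of the list CTAWWWWTAG raised most margins. For the consensus margin, the values were, at round 1, 2.39 (wild type), 3.41 (K4E), 3.69 (K5E), 3.83 (R15G) and 2.02 (K23R), and at round 2, 2.25 (wild type), 2.45 (K4E), 2.02 (K5E), 2.39 (R15G) and 1.18 (K23R).

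A count minimum of 200 was added after seeing the data. Values of the consensus margin were, at round 1, 1.30 (wild type), 1.92 (K5E), 2.83 (R15G) and 1.20 (K23R), and at round 2, 1.59 (wild type), 0.77 (K4E), 0.84 (K5E), 1.65 (R15G) and 0.67 (K23R). For the outer base preference, the values were, at round 2, 2.75 (K4E) and 1.93 (K5E). Values of the consensus margin minus that of wild type were, at round 1, 0.58 (K4E), 0.61 (K5E), 1.52 (R15G) and -0.10 (K23R), and at round 2, -0.82 (K4E), -0.75 (K5E) and 0.062 (R15G). For the outer base preference minus that of wild type, the values were, at round 2, 1.97 (K4E) and 1.15 (K5E). The correlation between rounds was 0.834 in K4E, 0.842 in K5E and 0.786 in K23R. The correlation between proteins was, at round 1, 0.644 (wild type and K4E), 0.664 (wild type and K5E), 0.826 (wild type and R15G), 0.480 (wild type and K23R), 0.945 (K4E and K5E), 0.793 (K4E and R15G), 0.709 (K4E and K23R), 0.779 (K5E and R15G), 0.690 (K5E and K23R) and 0.845 (R15G and K23R), and at round 2, 0.596 (wild type and K5E), 0.899 (K4E and K5E), 0.584 (K4E and R15G), 0.502 (K4E and K23R), 0.566 (K5E and R15G) and 0.487 (K5E and K23R). The SD between strands was, at round 1, 0.232 (wild type), 0.274 (K4E), 0.270 (K5E), 0.197 (R15G) and 0.160 (K23R), and at round 2, 0.299 (K4E), 0.281 (K5E), 0.209 (R15G) and 0.082 (K23R).

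The library average as background was also added after seeing the data. The consensus margin was, at round 1, 2.997 (wild type), 3.63 (R15G) and 2.17 (K23R), and at round 2, 2.68 (wild type), 2.47 (K4E), 2.30 (K5E), 3.39 (R15G) and 2.27 (K23R). The consensus margin minus that of wild type was, at round 1, -1.11 (K4E), -0.51 (K5E), 0.64 (R15G) and -0.83 (K23R), and at round 2, -0.21 (K4E), -0.38 (K5E), 0.71 (R15G) and -0.41 (K23R).

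Enrichment without the root doubled values at round 2 by construction. For the consensus margin, the values were, at round 2, 4.00 (wild type), 2.56 (K4E), 2.03 (K5E), 4.16 (R15G) and 2.17 (K23R). Values of the margin of the spacing of 3 were, at round 2, 3.16 (wild type), 1.16 (K4E), 0.80 (K5E), 2.22 (R15G) and 0.92 (K23R). Values of the margin of the spacing of 5 were, at round 2, 0.74 (wild type), -0.77 (K4E), -0.72 (K5E), 0.19 (R15G) and 0.44 (K23R). Values of the CArG margin were, at round 2, 1.98 (wild type), 0.87 (K4E), 0.55 (K5E), 0.73 (R15G) and 0.41 (K23R). Values of the margin of A or T only were, at round 2, 1.24 (wild type), -0.33 (K4E), -0.17 (K5E), 0.79 (R15G) and 0.57 (K23R). Values of the outer base preference were, at round 2, 1.57 (wild type), 5.64 (K4E), 4.06 (K5E), 1.82 (R15G) and 0.42 (K23R). For the mean loss at positions 1 and 10, the values were, at round 2, -0.43 (wild type), -2.84 (K4E), -1.90 (K5E), -0.74 (R15G) and -0.23 (K23R). For the mean loss at the TA steps, the values were, at round 2, -2.31 (wild type), -4.11 (K4E), -3.27 (K5E), -3.11 (R15G) and -1.58 (K23R). For the mean loss at positions 4 to 7, the values were, at round 2, -2.21 (wild type), -4.55 (K4E), -3.41 (K5E), -3.04 (R15G) and -1.91 (K23R). The mean losses of K4E and K5E at round 2 rest on the 26.4% and 28.2% of substituted 10-mers that were listed, so they are not comparable with the others. The central TpA effect was, at round 2, 0.21 (K4E), 0.83 (K5E), 0.19 (R15G) and 0.30 (K23R). Values of the outer base preference minus that of wild type were, at round 2, 4.07 (K4E), 2.49 (K5E), 0.25 (R15G) and -1.15 (K23R). The central TpA effect minus that of wild type was, at round 2, 0.19 (K4E), 0.81 (K5E), 0.17 (R15G) and 0.28 (K23R). For the consensus margin minus that of wild type, the values were, at round 2, -1.44 (K4E), -1.97 (K5E), 0.16 (R15G) and -1.83 (K23R).

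All sites matched on flanks gave other TpA effects. The central TpA effect was, at round 1, 0.49 (K5E) and 0.16 (R15G), and at round 2, 0.10 (wild type), 0.23 (R15G) and 0.20 (K23R).

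Unlisted 10-mers set to a count of 99, added after seeing the data, gave lower bounds. The outer base preference was, at round 2, 2.77 (K4E) and 2.11 (K5E). The outer base preference minus that of wild type was, at round 2, 1.98 (K4E) and 1.32 (K5E).

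The top 200 10-mers replaced the top 50. The percentage holding the core was, at round 1, 79.0 (R15G) and 84.0 (K23R), and at round 2, 26.0 (K4E), 31.0 (K5E), 81.5 (R15G) and 92.5 (K23R).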

Other observations

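The test of sites completed by the 5' flank and its rival were planned before the result was seen, whereas the lists described first and the decision to treat the rival test as void were chosen after.

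Sequences that join one end of the MEF2 site to one end of the CArG box were good ligands of wild type and R15G. The 64 10-mers CTAWWWWWGG and CCWWWWWTAG had a median enrichment of 9.12-fold in wild type at round 1, 94.6% of that of CTAWWWWTAG. The share was 84.4% in R15G, 77.9% in K23R, 50.2% in K4E and 48.6% in K5E. At round 2 it was 79.1% in wild type, 42.7% in R15G, 39.7% in K23R, 23.9% in K5E and 21.2% in K4E. These shares compare enrichment without the root, so at round 2 they carry both rounds of selection. A lower share at round 2 than at round 1 therefore does not by itself show poorer binding of these sequences. Single hybrids ranked near the top even in K4E, where CTATTTTTGG was enriched 15.5-fold at round 1 and 312-fold at round 2.

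At round 1 K23R took sites with A and T at both outer positions as readily as those with C and G, but not at round 2. ATAWWWWTAT had a median of 4.62-fold in K23R at round 1, beside 4.25-fold for CTAWWWWTAG, and of 19.1-fold beside 26.4-fold at round 2. In K4E the medians at round 1 were 1.55-fold and 11.01-fold, in K5E 2.31-fold and 13.2-fold, in R15G 9.57-fold and 13.3-fold, and in wild type 5.46-fold and 9.64-fold. In K4E and K5E a single matching outer base gave intermediate values, with 3.86-fold and 5.77-fold for TTAWWWWTAG.

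A hypothesis that the fixed 5' flank, which ends in C, supplies the first base of a site at the edge of the random region was not borne out. It requires TAWWWWTAGN to be more enriched than its reverse complement in K4E and K5E, where an outer C mattered most. The median log2 difference was -0.012 and 0.14 in K4E and -0.043 and 0.064 in K5E at rounds 1 and 2, so that the lowest of the 4 values was -0.043. The rival, a strand bias of the pool or the sequencing, was measured on the consensus sites of K4E at round 1, which gave a median of 0.055 with an SD of 0.19. This met the criterion set in advance, but only because the difference to be accounted for lay near 0, so the test was treated as void and the rival stays undecided.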
